A study of Homo sapiens with 2 samples.

How the data were processed

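Total RNA of PK59 cells (labelled non-CSC, 1 sample) and of PK59 cancer stem cells (labelled CSC, 1 sample) was labelled with Cy3 from 0.1 µg and hybridised to 1-colour Agilent arrays. Per the labels, CSC were sorted for high ALDH1A1 and kept for 7 days in low-attachment plates with 2% B27, 10 ng/ml EGF and 10 ng/ml FGF, and spheres were passaged every 4 to 7 days. The same protocol text stands under both samples, and how the non-CSC sample was cultured is not stated apart. Both arrays lay on the same slide (slide 1), so slide did not differ between the groups.

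Intensity values were deposited as scanner output for each array. Per the file headers and the submitters' processing notes, they were made with Agilent Feature Extraction 12.0.3.1, which subtracted the background and removed spatial trends within each array without scaling between arrays. The files give a processed signal, its error, the median signal of the spot and of its local background, and flags of 0 or 1 per spot for outliers, saturation and signal well above background, also as deposited. The authors' value table holds linear intensity for 34439 of the spots. Its values equalled the processed signal times 1 factor per array within a relative tolerance of 1e-06 for all 34439 rows, with a factor of 3.44 for non-CSC (median 617) and 3.62 for CSC (median 693). The scale was therefore linear with no centring of genes and no change of direction. Which statistic set the factors is not given in the sources used here.

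Each array had 62976 spots, of which 60901 were not controls. Spots flagged as outliers (110 on the non-CSC array, 126 on the CSC array) were left out, and 0 spots were saturated. The value used was log2 of the processed signal minus the array's 75th percentile of it over non-control spots, which was 282 for non-CSC and 303 for CSC. Spots of 1 probe were averaged. A probe counted as well above background on an array where at least 50% of its spots carried that flag. The lowest signal well above background was 10.5 on the non-CSC array and 8.53 on the CSC array, which limits how far a dim gene can be followed.

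The scanner files used here pair probes with transcript accessions and not with gene symbols. Accessions were matched, without versions, to the RefSeq gene table of GRCh38.p14, which was used for names and chromosomes alone since the array design names an older build. Of 58199 probes, 31102 had 1 symbol, 0 several and 27097 none. The 94 probes of chromosome Y genes, XIST and TSIX were left out. The named probes covered 22374 genes. A gene was represented by the brightest of its probes measured on both arrays, which gave 14062 genes; 5820 were above background on neither array and 7 were above background on each array through different probes. Of 3667 genes with more than 1 such probe, 206 had probes that differed in direction with at least one at 2-fold. Probes of near-identical genes can read each other's transcripts, which concerns the metallothioneins, histones, KRT6A and KRT6B, SAA1 and SAA2, HSPA1A and HSPA1B, and ANXA8 and ANXA8L1.

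The comparison was CSC minus non-CSC. With 1 array per group no test was possible, so genes were counted by size, at least 2-fold (1 on the log2 scale), and the difference has no replicate check. The technical error combines the scanner's signal errors of both arrays and covers 1 hybridisation of 1 RNA. For a gene above background on 1 array, the fold is a lower bound. It sets the bright array's value against the higher of the dim probe's own value and the lowest signal well above background on the dim array. The number of arrays limits the precision of every value.

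Before the data were examined, 43 gene lists with 883 entries were fixed, of which 864 had a probe, together with the alternatives and the rule for naming genes. Each list's median was set against 10000 random lists of the same size, matched in 20 bins of mean level, as a description of these arrays. Named genes were ALDH1A1, the 12 highest and 12 lowest differences among genes measured on both arrays (more than 2 times the technical error, with the same direction under normexp), the 5 highest bounds on each array, every voltage-gated potassium channel alpha subunit above background on at least 1 array, and the 2 highest and 2 lowest members of each other list. Other members named beside a list were chosen after their values were seen. Some genes that the rule takes are not reported here.

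The steps were tested on simulated arrays built from the real signals and errors. Of 200 planted genes, 50 at 1.5, 45 at 3, 50 at -1.5 and 48 at -3 log2 units were measured on both arrays among 15436 genes, and at each size 100% of them were counted. In a simulated pair with no change, 124 of 15451 genes lay at least 2-fold apart. The simulated noise was the scanner's error alone, with no difference between cultures, RNA preparations or labellings. Detection was a single signal cut in place of the scanner's flag. The 124 genes therefore give no rate of false calls for the real arrays. Of 100 random lists 4 fell outside the central range, and a planted list lay at percentile 100. These random lists were drawn from the same genes they were set against. The simulation thus checks the computation and not the design with 1 array per group.

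Alternatives were normexp background correction (offset 50), other scalings (75th percentile over probes above background, median of all probes, quantile normalization, reference genes, cyclic loess, the authors' value table), the median of a gene's probes, no filter on dim probes, a signal of at least 100 on both arrays, a 3-fold size, a difference beyond 2 times the technical error, another detection flag and a 3-fold bound. Normexp had been planned on mean spot signals and was run on median spot signals, the ones in the files used here. Centring on the spike-in probes was added after seeing the data. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.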

Results

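The series holds 1 microarray of PK59 cells and 1 of PK59 cancer stem cells (CSC), both hybridised with Cy3-labelled cRNA on a 1-colour Agilent whole-transcriptome design. PK59 is an established human pancreatic cancer cell line. The labels call the first sample non-CSC and the second CSC. Per the labels, CSC were cells with high levels of the aldehyde dehydrogenase ALDH1A1, taken by fluorescence-activated sorting and grown as floating spheres. The title of the series asks what voltage-gated potassium channels do in keeping pancreatic CSC in their state. With 1 array per group there was no spread between replicates, so no difference below has a p-value. Differences are given as CSC minus non-CSC in log2 units unless a fold is named. Each value describes these 2 arrays, and the errors given after ± are technical errors of 1 hybridisation from the scanner's error model. Of 60901 spots that were not controls, 30547 (50.2%) were well above background on the non-CSC array and 31704 (52.1%) on the CSC array. Replicate spots of 1 probe had a pooled SD of 0.06 log2 units on the non-CSC array and 0.07 on the CSC array.

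ALDH1A1, the marker used for sorting, was well above background on the CSC array and not on the non-CSC array. Its brighter probe was at least 9.26-fold higher on the CSC array, with a processed signal of 104 against 5.53. Its second probe was at least 1.54-fold higher, with a signal of 17.2 against 6.73. With normexp background correction the bound of the brighter probe was 1.12 on the log2 scale in place of 3.21. This gene follows the sort and is no independent finding. The other aldehyde dehydrogenases went both ways. Of 13 family members measured on both arrays, 1 was at least 2-fold higher on the CSC array and 5 were at least 2-fold lower. ALDH5A1, which oxidises succinate semialdehyde, was higher by 1.40 ± 0.21 log2 units, and by 0.92 with normexp correction, which is under 2-fold. ALDH1A3, like ALDH1A1 a retinaldehyde-oxidising enzyme, differed by -7.37 ± 0.20, and ALDH3B1 by -4.60 ± 0.22. The median of the family was 0.10 and its mean -1.15, and the median was -0.17 when all probes of a gene were used, so the family as a whole has no settled direction. Its median lay at percentile 53.6 of 10000 random gene lists matched on size and signal level.

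Across all genes the arrays differed widely. The CSC array had lower signals for epithelial junction and keratin genes, basal keratinocyte genes and mucin-associated genes, and higher signals for neural and neuroendocrine genes, N-cadherin, vimentin and cholesterol synthesis genes. Of 14062 genes measured on both arrays, 2552 (18.1%) were at least 2-fold higher on the CSC array and 2459 (17.5%) at least 2-fold lower. At least 16-fold differences were found for 177 higher and 330 lower genes. A further 836 genes were well above background on the CSC array alone with a bound of at least 2-fold, and 891 on the non-CSC array alone. The difference had a median of 0.01 and an SD of 1.63 log2 units across genes, against a median technical error of 0.20. That error holds no variation between cultures, RNA preparations or labellings, so it does not show how much of the spread belongs to the groups. The arrays also differed by chromosome, with a median of -0.87 over the 252 genes of chromosome 13, -0.57 on chromosome 18, -0.55 on chromosome 20, -0.53 on chromosome 8 and 0.30 on chromosome 5. Pearson's r of the arrays was 0.84 across genes, which are not independent replicates. The split of higher and lower genes depends on the scaling. With the authors' factors the median of all genes lay 0.17 higher than in the main setting, and 3046 genes were higher and 2073 lower (59.5% higher, against 50.9%).

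The genes with the lowest differences were S100P, a calcium-binding protein (-12.88 ± 0.27), WFDC2, a secreted protein with protease-inhibitor domains (-12.02 ± 0.30), and the imprinted non-coding RNA H19 (-11.95 ± 0.24). Next came ANXA8L1 (-11.15 ± 0.23), whose probe may also read the near-identical ANXA8, and PLAT, tissue plasminogen activator (-11.15 ± 0.28). The glycosyltransferase B3GNT3, the trefoil peptide TFF2, INHBB, KRT13, DEFB1 and CLDN4 were also among the lowest, between -11.05 and -9.77. The highest differences were those of CBS, an enzyme of transsulfuration (9.72 ± 0.27), the secretory granule protein SCG2 (9.72 ± 0.24), the connexin GJC1 (9.13 ± 0.26), the lipoprotein component APOE (9.05 ± 0.20) and the TNF-family ligand CD70 (8.87 ± 0.26). HEY1, PDE4B, NKAIN1, NTNG2, REEP2, APC2 and MAP2 lay between 8.61 and 7.76. Well above background on the CSC array alone, LDHB was at least 4299.8-fold higher, BEX3 at least 2319-fold, the transcription factor SOX2 at least 2251-fold, TCEAL4 at least 1689.8-fold and GNG11 at least 1309.7-fold. On the non-CSC array alone, the keratin KRT6A was at least 9384-fold brighter, ADIRF at least 6263-fold, CEACAM6 at least 5741-fold and FXYD3 at least 5387-fold. Normexp background correction gave smaller sizes for these genes, such as -10.64 for S100P and 7.69 for CBS. It also shrank the differences of genes named below that were dim on one array, such as KLF4 (-3.21), MMP7 (2.84), FOXA2 (1.88) and PAX6 (1.12). The sizes and bounds given for such genes therefore hold for the processed signal alone.

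**Figure D1:**
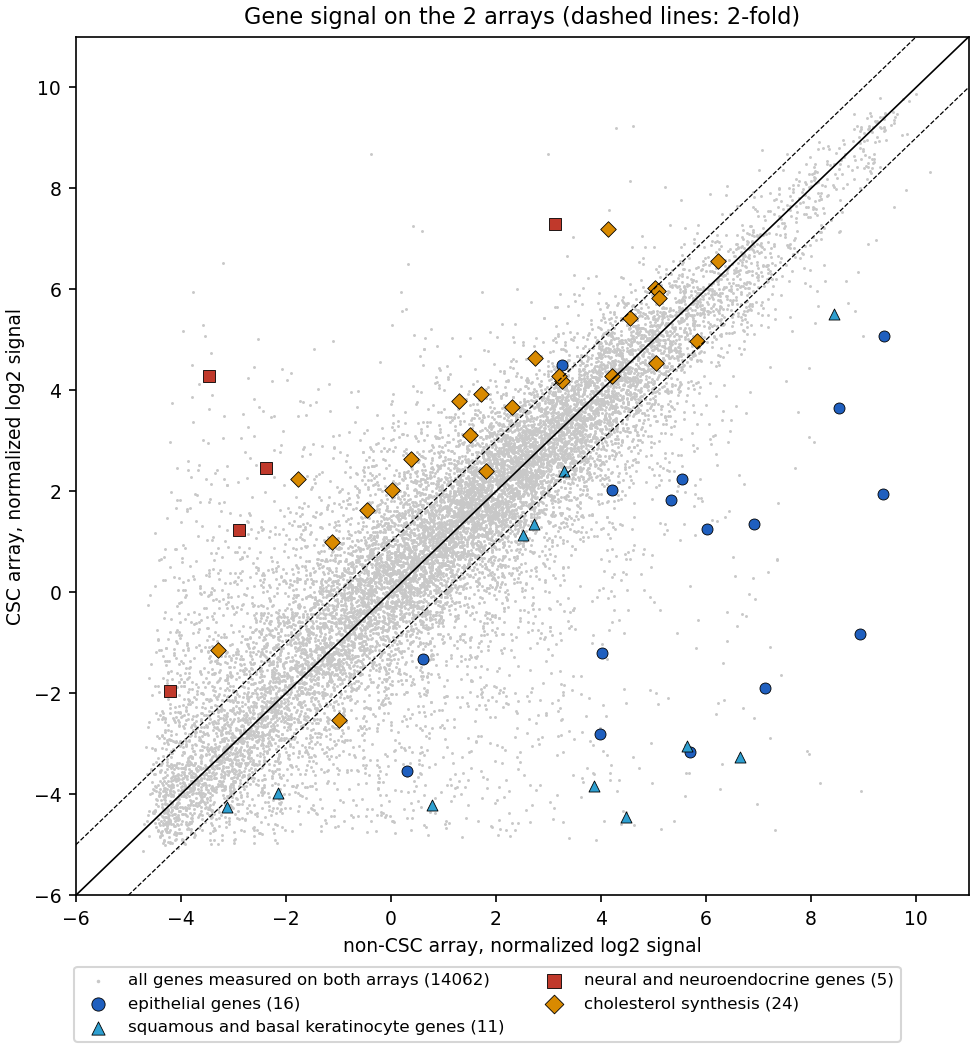
Normalized log2 signal of the 14062 genes measured on both arrays, non-CSC on the x axis and CSC on the y axis, with 4 gene lists marked; the solid line marks equal signal and the dashed lines 2-fold. Of 16 epithelial genes 15 lie below the lower dashed line, and all 5 neural and neuroendocrine genes lie above the upper one.

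Voltage-gated potassium channels, the channels that open on depolarisation and let potassium leave the cell, included members higher and members lower on the CSC array. All 40 alpha (pore-forming) subunit genes had probes, and 20 were above background on neither array. Of 9 measured on both arrays, 3 were at least 2-fold higher, 2 at least 2-fold lower and 4 within 2-fold. KCNG1, a modulatory subunit, had the highest difference (5.76 ± 0.21, 54.1-fold). KCNQ1 was also higher (1.65 ± 0.21). KCNH2, the hERG channel, was lower (-3.79 ± 0.20), and its second probe gave -2.19. KCNQ3 was lower as well (-1.42 ± 0.21), by less than 2-fold after normexp correction (-0.82). KCNC4 differed by 0.81 ± 0.26, KCNG4 by 0.39 ± 0.29 and KCNH3 by -0.29 ± 0.20.

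Another 7 alpha subunits were well above background on the CSC array alone. KCNG3 was at least 24.2-fold higher there, KCNF1 at least 13.3-fold, KCND1 at least 6.02-fold, KCNC1 at least 3.58-fold, KCNH1 (EAG1) at least 3.50-fold and KCNQ5 at least 2.56-fold. The 4 found on the non-CSC array alone were KCNS3 (at least 33.3-fold), KCNH8 (at least 10.9-fold), KCNS1 (at least 7.82-fold) and KCNA3 (at least 1.38-fold). With normexp correction the bounds of KCND1 (0.93), KCNC1 (0.57), KCNH1 (0.57), KCNQ5 (0.27) and KCNS1 (-0.97) were under 2-fold (log2 values in brackets). Those of KCNG3 (2.22), KCNF1 (1.67), KCNS3 (-2.45) and KCNH8 (-1.23) stayed above 2-fold but were smaller. The folds given for KCNG3 and KCNC1 come from the brightest probe of each gene. On the CSC array a dimmer KCNG3 probe had a processed signal of 26.3, against 271 for the brightest. For KCNC1 these signals were 15.2 and 40.1, and its other probe was above background on neither array. The dimmer probes of both genes give smaller bounds. The median difference of the 9 alpha subunits was 0.81 log2 units, at percentile 95.0 of matched random lists. It was 1.09 with single-array members set at their bounds, -0.21 with no filter on dim probes and -0.29 over the members with a signal of at least 100 on both arrays, so the direction of the family depends on how dim probes are treated.

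**Figure D2:**
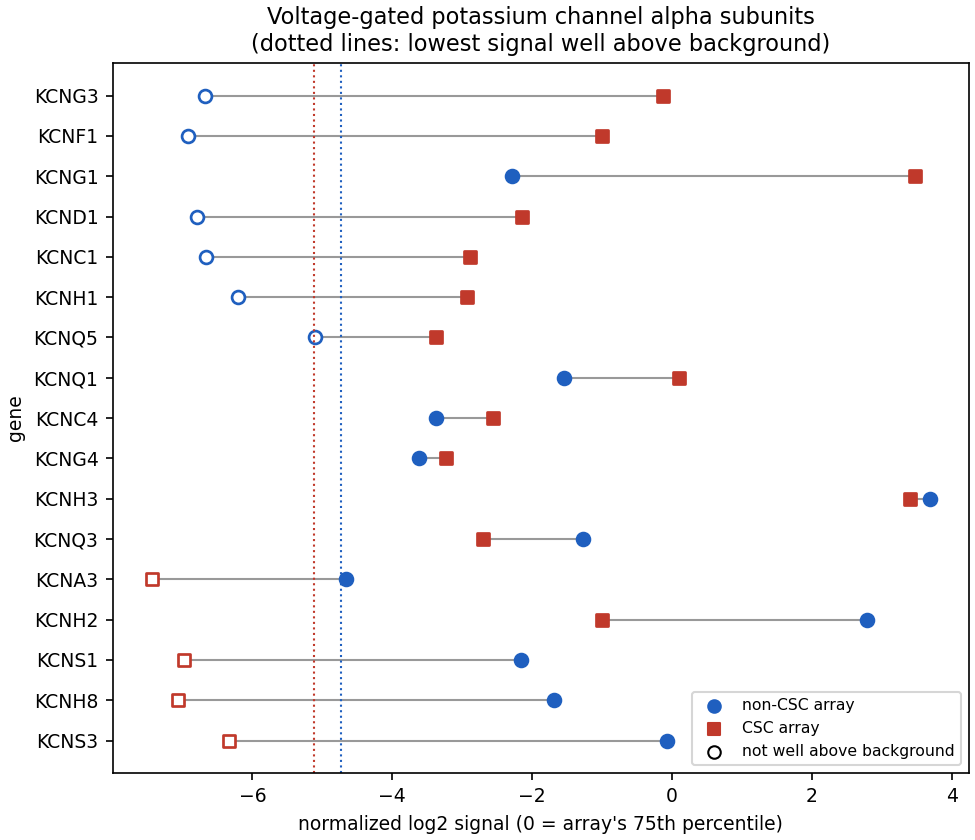
Normalized log2 signal (x axis, 0 is the array's 75th percentile) of the 17 voltage-gated potassium channel alpha subunits named in the text, non-CSC as circles and CSC as squares, joined by a line per gene. Open symbols were not well above background, which applies to 6 of them on the non-CSC array and 4 on the CSC array, and dotted lines mark the lowest signal well above background on each array.

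Of 5 accessory subunits of these channels measured on both arrays, 3 were at least 2-fold lower and 0 higher, namely the beta subunits KCNAB2 (-1.56 ± 0.26) and KCNAB3 (-1.40 ± 0.33) and the calcium-binding KCNIP3 (-1.05 ± 0.21). KCNE4 was at least 28.5-fold lower, KCNIP2 at least 3.22-fold lower and KCNE2 at least 2.98-fold higher on the CSC array. With normexp correction KCNAB2 (-0.61) and KCNAB3 (-0.42) were within 2-fold. The median was -1.05 (percentile 4.39), and -0.42 with normexp correction. Among 13 other potassium channels, 3 were at least 2-fold higher and 5 at least 2-fold lower. The large-conductance channel KCNMA1 (2.94 ± 0.20) and its subunit KCNMB3 (2.34 ± 0.24, and 1.06 with normexp correction) were higher, and the leak channels KCNK1 (-4.03 ± 0.20) and KCNK6 (-2.73 ± 0.22) were lower. Their median was -0.70 (percentile 1.89) and 0.07 with single-array members at their bounds. Of 11 voltage-gated sodium and calcium channel genes, 3 were at least 2-fold higher and 0 at least 2-fold lower, with the T-type calcium channel CACNA1H highest (3.26 ± 0.22, and 2.23 with normexp correction). Another 7 were above background on the CSC array alone, 5 of them with a bound of at least 2-fold, and 0 on the non-CSC array alone. The median of these 11 genes was 0.28 (percentile 81.4), and -0.01 with normexp correction.

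Epithelial genes were far lower on the CSC array. Of 16 measured on both arrays, 15 were at least 2-fold lower, with a median of -4.82 (28.2-fold lower), below the medians of all 10000 matched random lists. The tight junction gene CLDN4 differed by -9.77 ± 0.20, the adhesion molecule EPCAM by -9.03 ± 0.21, the simple-epithelium keratin KRT19 by -7.42 ± 0.20 and E-cadherin (CDH1) by -4.75 ± 0.20. P-cadherin (CDH3) was the one member at least 2-fold higher (1.25 ± 0.20). The epithelial transcription factors ELF3, OVOL1 and GRHL2 and the trafficking protein RAB25 were above background on the non-CSC array alone. Of 11 squamous and basal keratinocyte genes, 10 were at least 2-fold lower and 0 higher (median -2.92), with KRT13 at -9.91 ± 0.22 and KRT14 at -8.93 ± 0.28. Another 12 members, among them KRT5, KRT17 and LY6D, were found on the non-CSC array alone. Over members with a signal of at least 100 on both arrays the median of this list was -1.37, and with no filter on dim probes -6.82. Of 12 mucin and gastric-type genes, 7 were at least 2-fold lower and 0 higher (median -2.65, and -4.66 with no filter), with TFF2 at -10.16 ± 0.26, CEACAM1 at -7.72 ± 0.21 (-6.92 over all its probes) and MUC1 at -4.81. CEACAM6, AGR2 and GKN1 were among 6 members found on the non-CSC array alone. Of 10 pancreatic duct genes 6 were at least 2-fold lower (median -3.91, and -0.57 with no filter), whereas the phosphoprotein SPP1 (3.31 ± 0.20) and the transcription factor FOXA2 (3.73 ± 0.27) were higher. The squamous, mucin and duct medians were also below those of all 10000 matched random lists.

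Genes for attachment to the matrix were lower too. Of 23 cell adhesion and matrix genes, 18 were at least 2-fold lower and 2 higher, with a median of -2.23 that lay below all matched random lists and was -2.95 with no filter. The laminin chain LAMA3 was lower (-7.27 ± 0.20, and -4.53 over all its probes), and its second probe gave -1.80. The urokinase gene PLAU was higher (6.84 ± 0.20). Of 13 matrix proteases and their inhibitors, 8 were at least 2-fold lower and 3 higher (median -1.28, percentile 0.06). MMP7 (4.97 ± 0.30) and MMP10 (4.19 ± 0.20) were higher, whereas ADAM8 (-4.22 ± 0.20, and -2.29 over all its probes) and MMP1 (-4.04 ± 0.20) were lower. The second ADAM8 probe gave -0.36, which is within 2-fold. The inhibitor TIMP3 was at least 519-fold lower, above background on the non-CSC array alone.

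Mesenchymal genes did not move as 1 group. Of 10 measured on both arrays, 5 were at least 2-fold higher and 3 at least 2-fold lower. N-cadherin (CDH2) was higher by 7.54 ± 0.22, the intermediate filament vimentin (VIM) by 4.62 ± 0.20 and the transcription factor ZEB1 by 3.96 ± 0.21. The calcium-binding protein S100A4 (-9.05 ± 0.21), the actin-binding protein TAGLN (-3.99 ± 0.21) and collagen COL1A1 (-2.33 ± 0.21) were lower. Fibronectin (FN1) and SNAI2 were above background on the non-CSC array alone, at least 89.5-fold and 83.3-fold brighter there, and LOX and SPARC on the CSC array alone, at least 4.30-fold and 1.82-fold. The median of the list was 0.95 (percentile 98.3) and -0.38 with no filter on dim probes, and 2.03 over members with a signal of at least 100 on both arrays. That last filter dropped S100A4, TAGLN and COL1A1 for their low CSC signal, and CDH2 and ITGB3 for their low non-CSC signal.

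The neural and neuroendocrine genes that were detected were higher, while 7 of the 16 on the list were above background on neither array. All 5 measured on both arrays were at least 2-fold higher (median 4.17, above all 10000 matched random lists, and 3.20 with no filter), with the microtubule protein MAP2 at 7.76 ± 0.25, ENO2 at 4.85 ± 0.21, the neuronal tubulin TUBB3 at 4.17 ± 0.20 and the synaptic protein SNAP25 at 4.14 ± 0.23. The other member, SYN1, differed by 2.27 ± 0.32, and by 0.76 with normexp correction, which is under 2-fold. GAP43, SYP, UCHL1 and NCAM1 were above background on the CSC array alone. Of 8 pancreatic endocrine genes, 2 were at least 2-fold higher, SCG2 and the transcription factor PAX6 (2.83 ± 0.34), and 1 was at least 2-fold lower. CHGB was at least 185-fold higher, and INS at least 16.5-fold lower, each above background on a single array. The median of that list was 0.03 (percentile 49.1) and -0.02 with normexp correction. Of 4 pancreatic acinar genes, NR5A2 was higher (2.51 ± 0.20) and PRSS3 lower (-8.59 ± 0.32), with a median of -0.69 (percentile 12.3). The acinar median was 0.94 over NR5A2 and CEL, the only members with a signal of at least 100 on both arrays.

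Markers used for pancreatic CSC went both ways. Of 13 CSC markers measured on both arrays, 2 were at least 2-fold higher and 6 at least 2-fold lower. The chemokine receptor CXCR4 (3.36 ± 0.21) and the RNA-binding protein MSI2 (1.41 ± 0.20) were higher, whereas EPCAM, CD24 (-6.71 ± 0.20), DCLK1 (-4.56) and ABCG2 (-3.53, and -2.01 with normexp correction) were lower. CD44 differed by 0.92. TSPAN8 was at least 316-fold lower, above background on the non-CSC array alone. The median was -0.30 (percentile 18.8) and 0.70 over members with a signal of at least 100 on both arrays. That filter dropped EPCAM, DCLK1, ABCG2 and MSI1 for their low CSC signal, and CXCR4 for its low non-CSC signal. The change of sign is therefore no separate evidence on the direction of the list. Among pluripotency factors SOX2 and LIN28B (at least 30.9-fold) were above background on the CSC array alone. Of 5 measured on both arrays, 3 were at least 2-fold lower and 0 higher, with KLF4 at -5.57 ± 0.30, SALL4 at -1.47 and POU5F1 at -1.93 ± 0.21, whose probes differ in direction (-0.92 over all of them). Their median was -1.47 (percentile 1.84), and -0.29 over MYC and BMI1, the only members with a signal of at least 100 on both arrays.

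Signalling lists associated with stem cells differed from each other. Of 6 Hedgehog pathway genes, 3 were at least 2-fold higher and 0 lower (median 1.42, percentile 98.3), namely the transcription factors GLI3 (3.44 ± 0.21) and GLI2 (2.24 ± 0.21) and the receptor PTCH1 (2.00). The median was 2.72 over GLI3 and PTCH1, the only members with a signal of at least 100 on both arrays. The signal transducer SMO and the target and effector GLI1 were at least 312-fold and 267-fold higher, above background on the CSC array alone, as was BOC (at least 2.58-fold). GAS1, a Hedgehog-binding surface protein, was at least 2.90-fold lower, above background on the non-CSC array alone. Of 14 Notch pathway genes, 4 were at least 2-fold higher, led by HEY1 and NOTCH3 (2.12 ± 0.20), and 5 lower, led by LFNG (-2.29 ± 0.20, and -1.47 over all its probes) and HES2 (-1.91). The second LFNG probe gave -0.66, which is within 2-fold. HEYL was at least 14.2-fold higher, above background on the CSC array alone. The Notch median was -0.29 (percentile 14.7, mean 0.35). Of 17 Wnt targets and receptors, 4 were at least 2-fold higher, with TCF7 at 3.72 ± 0.21 and AXIN2 at 1.42, and 3 lower, with SP5 at -4.46 ± 0.30 and FZD6 at -3.55. LEF1 was at least 20.4-fold higher, above background on the CSC array alone. With normexp correction AXIN2 was within 2-fold (0.65) and SP5 was at -2.28. The Wnt median was -0.41 (percentile 5.93) and 0.25 with no filter, and 0.03 with single-array members at their bounds.

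Genes of sterol synthesis were higher on the CSC array. Of 24 cholesterol synthesis genes, 13 were at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.22 (2.34-fold), above all 10000 matched random lists. The sterol-transport protein STARD4 was higher by 4.02 ± 0.21 and the sterol reductase DHCR7 by 3.06 ± 0.20. TM7SF2 had the lowest value (-1.54 ± 0.22, and -0.99 with normexp correction), and 1 further member was above background on the non-CSC array alone. Of 12 fatty acid synthesis genes, 5 were at least 2-fold higher and 0 lower (median 0.59, percentile 96.3), led by the desaturases FADS1 (5.27 ± 0.20) and FADS2 (3.60 ± 0.21). ME1 was at least 35.6-fold higher, above background on the CSC array alone.

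**Figure D3:**
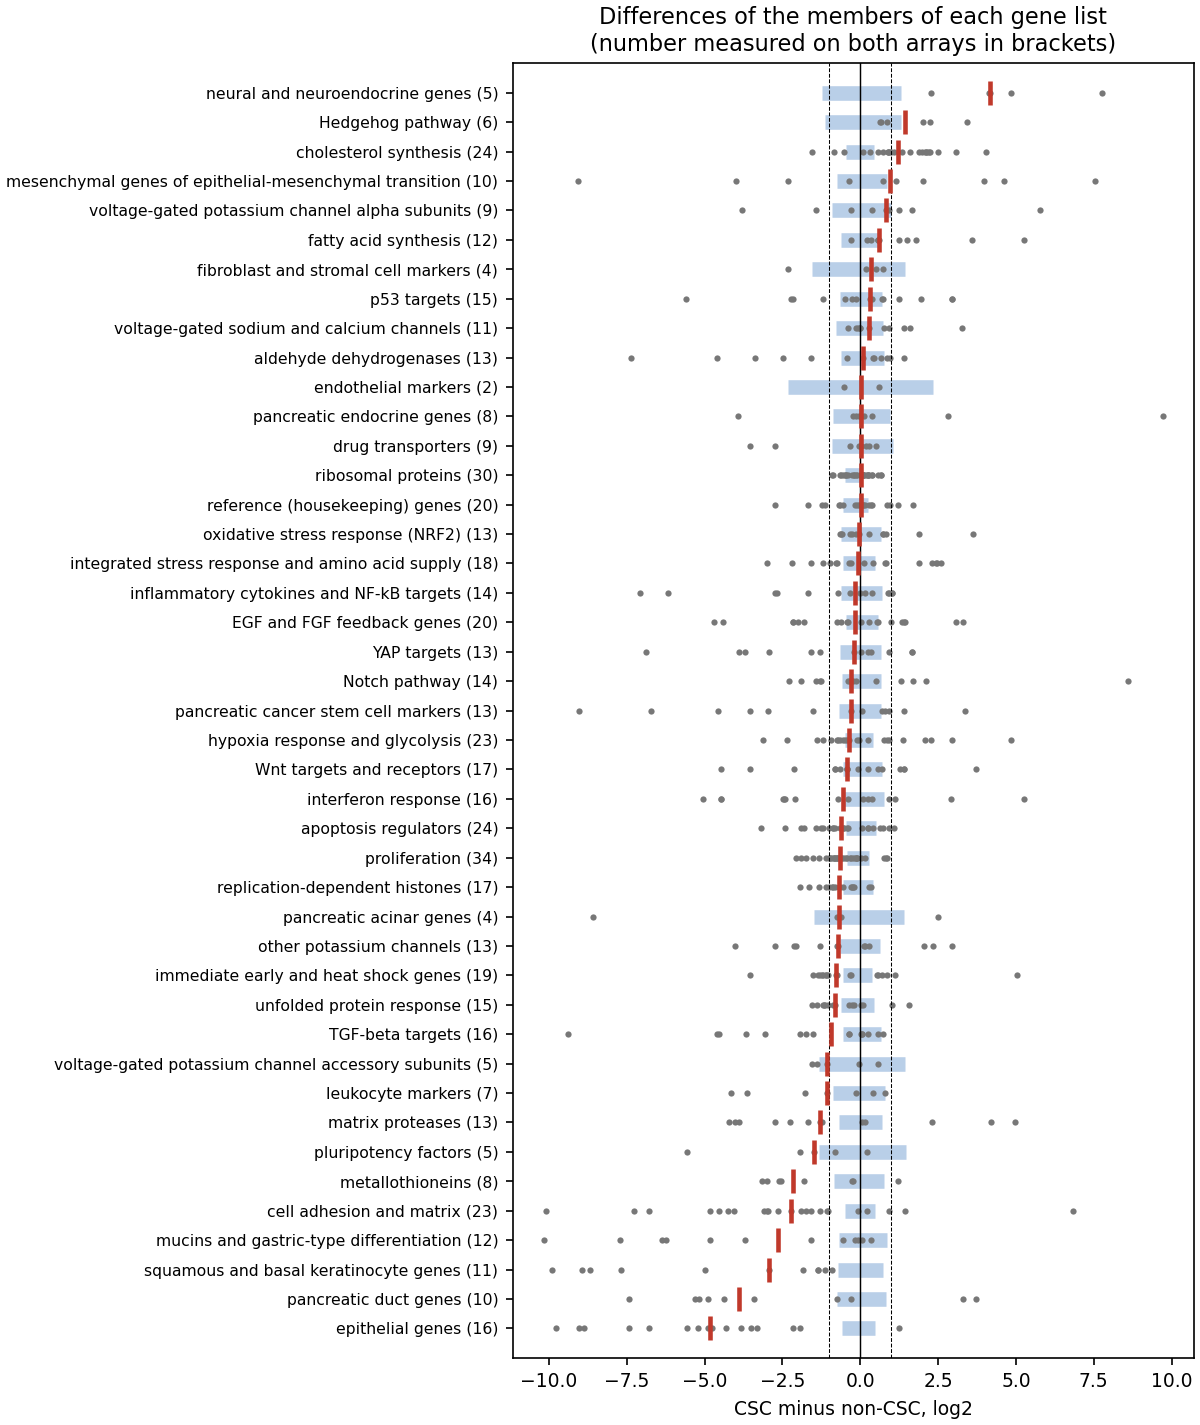
Gene lists by the CSC minus non-CSC difference (log2): each grey dot is a gene measured on both arrays, the red mark is the list's median, the blue bar spans the central part of the medians of 10000 matched random lists, and dashed lines mark 2-fold. The epithelial list lies lowest with a median of -4.82 and the neural and neuroendocrine list highest with 4.17.

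Proliferation genes were slightly lower as a list. Of 34, 0 were at least 2-fold higher and 6 at least 2-fold lower (median -0.64, percentile 0.10), with the replication gene MCM4 at -2.05 and TYMS at -1.89 lowest and MKI67 at -0.14. Of 17 replication-dependent histone genes, 0 were higher and 5 lower (median -0.67, percentile 0.98), with H3C4 at -1.92. All 30 ribosomal protein genes lay within 2-fold (median 0.02, percentile 95.2, mean -0.07). Of 20 reference genes, 14 lay within 2-fold (median 0.02, percentile 77.1, mean -0.15). GAPDH was higher by 1.69 ± 0.20 and HPRT1 by 1.21, while TFRC (-2.75) and YWHAZ (-1.66) were lower.

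Markers of other cell types did not move together. Of 7 leukocyte markers measured on both arrays, 0 were at least 2-fold higher and 4 lower (median -1.07, percentile 0.99, and -0.36 with normexp correction), with CSF1R at -4.16 ± 0.24 (-2.52 with that correction) and CD14 at -3.64 ± 0.21. Of 4 fibroblast markers, 0 were higher and 1, COL1A1, was lower (median 0.34, percentile 71.5, mean -0.22, and -0.37 with no filter). On the non-CSC array alone, DCN was at least 16.9-fold and POSTN at least 2.76-fold brighter, and on the CSC array alone PDGFRA was at least 2.38-fold brighter. The endothelial markers CDH5 (-0.53) and VWF (0.60) were within 2-fold (median 0.04, percentile 47.0), and TEK was at least 10.9-fold higher on the CSC array.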

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

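The probes without a gene symbol were not used in the comparison of genes, and they also differed between the arrays. Of 6654 such probes measured on both arrays, 709 (10.7%) were at least 2-fold higher on the CSC array and 953 (14.3%) at least 2-fold lower. These results stand out because they come from probes outside the main comparison. They have no gene names here, and no explanation for them was tested.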

How the results depend on the processing

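One alternative, centring on the spike-in probes, was chosen after seeing the data. No paired analysis was possible because each group has 1 array. Leaving out an array was ruled out for the same reason. Of the values of 7 main results under the alternatives, 50 kept their size within the limits set and 17 moved. For 43 list medians these counts were 405 and 66, and for 211 named genes 1996 and 172. None was labelled reversed. That label was open only to differences and medians of at least 2-fold in the main setting, and not to counts of genes. Scalings that shift all genes alike moved them by at most 0.17. The limit for list medians and named genes was 0.20 or more, so neither could move under these scalings. Many of the values that kept their size were thus fixed in advance.

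Without a filter on dim probes, 4109 genes were at least 2-fold higher and 4067 lower, with 11 higher and 7 lower alpha subunits of voltage-gated potassium channels, and the ALDH1A1 difference was 4.13. With a signal of at least 100 on both arrays these counts were 1562 and 1551 genes and 1 and 1 alpha subunits, since fewer genes enter. That filter drops genes for being dim on either array, and so can drop them because they differ. List medians under it are therefore no separate check of size or direction. At 3-fold, 1337 genes were higher and 1401 lower, with 1 alpha subunit lower. With normexp correction 1 alpha subunit was lower, the ALDH1A1 bound was 1.12, and 458 genes were counted on the CSC array alone and 522 on the non-CSC array alone. That setting changed the correction and the spot signal it starts from, and it added an offset of 50 to every corrected signal. The offset exceeds the lowest signals well above background (10.5 on the non-CSC array and 8.53 on the CSC array). It therefore makes the differences of dim genes smaller by construction, and a fall under 2-fold there is no independent check. The share of each of these parts was not tested. Normexp correction gave 1902 higher and 1935 lower genes, of which 1880 and 1932 were among those of the main setting. The median over both ALDH1A1 probes gave a bound of 1.92. With the median of a gene's probes, 3 genes were counted on the opposite side of the main setting.

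Scaling moved the median of all genes by 0.17 with the authors' table and by 0.10 with the median of all probes (2842 higher, 2217 lower). Relative to the median of all genes, the epithelial list stayed between -5.19 and -4.55 and the cholesterol list between 1.06 and 1.29 over all alternatives, where scalings that shift all genes alike cannot move these values. Some list medians changed sign under at least 1 setting. Beside those given with their lists, they included 0.10 (integrated stress response, quantile normalization), 0.12 (NRF2, authors' table), -0.30 (p53, signal of at least 100) and -0.05 (drug transporters, no filter). With the median of a gene's probes the reference gene median was -0.08 and the endothelial one -0.26. The endothelial median was -0.39 with no filter, and with normexp correction it was -0.10 and the ribosomal protein median -0.0039. Without the filter the median of all 22374 genes was itself -0.20, so list medians in that setting carry a shift to lower values. The endothelial value there rests mostly on undetected genes, since 7 of 10 were above background on neither array. Signal over background limits the comparison for the 5820 genes above background on neither array.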

Other observations

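The test of chromosome medians was set out before its result was seen, and the tests on spike-ins, admixture, cholesterol scaling and swapped labels were chosen only after the result was seen. TGF-beta targets and many inflammatory genes were lower on the CSC array. Of 16 TGF-beta targets, 8 were at least 2-fold lower and 0 higher (median -0.94, percentile 0.14, with -0.38 over members with a signal of at least 100 and -1.51 with no filter), with the matrix protein TGFBI at -9.40 ± 0.21 and the ligand TGFB2 at -4.60 ± 0.31 (-2.36 with normexp correction). The receptor TGFBR1 was at least 34.8-fold lower, above background on the non-CSC array alone. Of 14 inflammatory genes, 5 were lower and 2 higher (median -0.17, percentile 25.5), with TNFAIP2 at -7.07 ± 0.20 lowest. Another 8, among them IL6, CXCL8, ICAM1 and LCN2, were above background on the non-CSC array alone, whereas the chemokine CCL2 was at least 461-fold higher on the CSC array. With such members at their bounds the median of that list was -2.33. Of 16 interferon response genes, 7 were lower and 3 higher (median -0.56, percentile 2.75), from OAS1 at -5.04 ± 0.26 (-3.08 with normexp correction) to MX1 at 5.25 ± 0.21. IFI44 was at least 8.18-fold and RSAD2 at least 2.97-fold higher, and MX2 at least 5.99-fold lower, each above background on a single array. YAP targets were 6 lower and 2 higher of 13 (median -0.19, percentile 25.2), with tissue factor (F3) at -6.87 ± 0.20 and the kinase NUAK2 at 1.67, and ANKRD1 was at least 222-fold lower, above background on the non-CSC array alone. EGF and FGF feedback genes were 6 lower and 5 higher of 20 (median -0.18, percentile 18.6), from the ligand AREG at -4.69 ± 0.20 to SPRY1 at 3.31 ± 0.20.

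Stress lists differed from each other. Of 15 unfolded protein response genes, 6 were lower and 2 higher (median -0.81, percentile 0.49), with the chaperone HSPA5 at -1.54 and DNAJB9 at 1.55. Of 19 immediate early and heat shock genes, 9 were lower and 2 higher (median -0.77, percentile 0.28), from FOS at -3.53 ± 0.20 to EGR2 at 5.04 ± 0.21. Of 8 metallothioneins, 5 were lower and 1 higher (median -2.17, below all 10000 matched random lists, and -1.08 with no filter), with MT1B at -3.16 ± 0.20. The integrated stress response went both ways, with 5 of 18 genes higher and 4 lower (median -0.09, percentile 41.9, mean 0.15), from SLC7A5 at -2.98 to DDIT3 at 2.58. The serine synthesis enzymes PSAT1 and PHGDH were at least 676-fold and 160.5-fold higher, above background on the CSC array alone. Of 13 NRF2 genes, 2 were higher, with HMOX1 at 3.61 ± 0.20, and 0 lower (median -0.05, percentile 43.2, mean 0.42), while AKR1C1 and AKR1C3 were above background on the non-CSC array alone (at least 54.7-fold and at least 317-fold) and ME1 on the CSC array alone (at least 35.6-fold). Of 23 hypoxia and glycolysis genes, 5 were higher, with ENO2 highest of those measured on both arrays, and 4 lower, with ADM at -3.11 (median -0.37, percentile 7.11, mean 0.14). BNIP3 (at least 335-fold) and the glucose transporter SLC2A3 (at least 66.7-fold) of this list were higher, above background on the CSC array alone. Apoptosis regulators were 8 lower and 1 higher of 24 (median -0.61, percentile 0.56), with BIK at -3.18 lowest and BCL2L11, whose probes differ in direction, at 1.09 (0.36 over all of them). Of 15 p53 targets, 4 were higher and 4 lower (median 0.31, percentile 79.4, mean -0.06), from SFN at -5.59 ± 0.20 to TP53INP1 at 2.96 ± 0.22. Of 9 drug transporters, 2 were lower, ABCG2 and ABCC3 (-2.74 ± 0.20), and 0 higher (median 0.03, percentile 45.5, mean -0.62). ABCA3 was at least 38.9-fold higher, above background on the CSC array alone.

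The lower epithelial signal on the CSC array could come from several sources. A difference in RNA amount, labelling or scaling is argued against by the spike-in probes, whose 8 bright members had a median difference of -0.046 (range -0.18 to 0.07). Admixture of other cells under 50% of the CSC sample would leave epithelial genes within 2-fold if its PK59 cells kept the non-CSC levels and gave as much RNA per cell. Neither condition was measured. The median of these genes was -4.82, which is the observation itself and no separate test of admixture. Cells of another line or clone on one of the arrays may be present: the SD of the medians of 22 autosomes was 0.34, against at most 0.09 in 10000 shuffles of genes among chromosomes, with chromosome 13 at -0.87 (252 genes, 77.8% below the median of all genes), 18 at -0.57, 20 at -0.55 and 8 at -0.53, and chromosome 5 at 0.30. The shuffles ignore that neighbouring genes can be regulated together, a clone selected within PK59 was not separated from another line, and an effect of the sort and of sphere culture stays open and was not tested.

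Higher cholesterol synthesis genes could reflect the scaling between the arrays. Over the scalings run, the list's median was lowest at 1.21 with centring on the reference genes, and it was 1.27 with centring on the spike-in probes. The technical error was 0.20 for 1 gene. Scalings that shift all genes alike moved them by at most 0.17, so none of these could cancel the median. The values show that the choice among the scalings run leaves the median above that error, and they are no separate test of scaling as a source. An effect of the sort or of the sphere medium stays open and was not tested, since the medium of the non-CSC sample is not described apart.

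A swap of the 2 labels would reverse the direction of every difference. ALDH1A1 goes with the labels, since 2 of 2 probes were well above background on the CSC array and 0 on the non-CSC array. This value is the observation itself and no separate test of it, and some CSC markers and aldehyde dehydrogenases run the other way (6 of 13 markers at least 2-fold lower, ALDH1A3 at -7.37), so a swap stays open.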
